A study of Homo sapiens with 2 samples.

How the data were processed

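Droplet-based single-cell RNA sequencing was available for 2 libraries of the RUES2 line, 1 called center and 1 called edge, taken 48 h after light. Per the file headers, the authors made the deposited UMI counts with Cell Ranger 4, as unfiltered matrices of 36601 genes by 2424975 barcodes for center and 2333876 for edge. The genome build and gene annotation of those counts are not given in the sources used here. Gene positions in the report come from GENCODE 29 on GRCh38 and were used for description only. No normalization of the counts by the authors is recorded in those sources.

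Everything else was computed from the raw counts. A barcode was called a cell if it had at least 1/10 of the 99th percentile of UMIs among the top barcodes, with the number of top barcodes chosen to lie near the number of cells returned (10400 in center and 11150 in edge). This gave 10420 cells with at least 5511.4 UMIs in center and 11167 with at least 4918.1 UMIs in edge, holding 91.5% and 91.8% of all UMIs. Cells with fewer than 1000 genes or more than 20% mitochondrial UMIs were removed, 1 in each library. The barcodes with the highest Scrublet scores were then removed as doublets at 0.8% per 1000 called cells, 869 in center and 998 in edge. The tool's own threshold would have removed 563 and 463. That left 9550 and 10168 cells.

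UMIs were summed over the kept cells of each library and divided by the library's sum to give CPM. A gene was measured if it had at least 20 CPM in 1 or both libraries. It was described as higher or lower if its ratio was at least 2-fold and the exact 95% counting interval excluded 1. Log2 ratios used a prior of 0.5 UMI scaled to library size. No test across samples was possible with 1 library per group, and no p-value was computed. On simulated libraries of the same depth, 100 of 100 genes set 3-fold apart were recovered, 0 of 7658 unaltered genes were called, and 95.2% of the intervals held the true ratio. That simulation covers counting error and not differences between cultures.

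The 27 gene lists, the cell filters, the comparisons and the rule for naming genes were fixed before the data were examined. A list with at least 3 measured members was given the percentile of its median log2 ratio among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Such percentiles carry no error rate, because genes of 1 list vary together. The named genes are the 12 with the largest log2 ratio in each direction among those with at least 50 CPM in the library where they are higher, leaving out unnamed transcripts, ribosomal and mitochondrial genes. To these were added up to 4 members of each list with the largest absolute ratio, BMP4 and 16 single markers. Within a class the 6 largest in each direction with at least 100 CPM were named. A gene that this rule names is not reported here. Other genes are named to complete a small count or beside a list's result, such as the ID genes, FST, SP5, the remaining hypoxia, chaperone and amnion genes and those of the SOX17 cells, and these were chosen after their values were seen.

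Both libraries were clustered together without integration, on log-normalized counts with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5. Genes were scaled before the components were computed. The leading genes of a cluster were the 30 with at least 30 CPM and the largest ratio of CPM to the mean of the other clusters, with 5 CPM added to both. A cluster was named after a cell type if at least 3 of that type's markers were among them and at least 3 were detected in at least 10% of its cells. Clusters with a median of UMIs outside 0.5 to 1.5 times that of all cells were not named. The markers were fixed in advance, but these thresholds of the naming were set with the data in hand. A class with at least 100 cells in each library was compared within itself. Shares of cells with a marker were computed after thinning each cell to 5000 UMIs, with exact 95% Clopper-Pearson intervals. Where no cell was seen, the limit given for the share is 3 cells of the total, which is tighter than the upper end of the exact interval (0.0386% for 0 of 9550). Barcodes with at most 100 UMIs served as the profile of free RNA.

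The alternatives covered the cell filters, doublet removal, scaling, the CPM minimum, subtraction of the free RNA profile, clustering resolution, separate clustering and thinning before clustering. Added after seeing the data were minima of 10000 and 2000 UMIs per barcode, removal of clusters outside the UMI limits, a wider amnion-like class and the comparison of clusters with at least 200 CPM of SOX2, taken from the unnamed and pluripotent-like clusters inside the UMI limits. Work was done in Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.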

Results

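The study used RUES2, an established human embryonic stem cell line, carrying a light-switchable source of BMP4. BMP4 is a secreted signalling protein that starts differentiation in models of the human gastrula. Doxycycline makes these cells sensitive to light, and light then triggers recombination between LoxP sites. Cells were taken 48 h after the light for droplet-based single-cell RNA sequencing of the 3′ ends of transcripts, in which each captured molecule carries a unique molecular identifier (UMI). There were 2 libraries. In the library called center, cells grew in regular culture without geometric confinement and the activated region was central. In the library called edge, cells grew on micropatterns and were activated at the edge. The title of the series frames the question as the interplay of tissue architecture and BMP4 at the onset of gastrulation. Culture geometry and the place of the light differed together, so a difference between the libraries cannot be assigned to either, or told apart from a difference between cultures or library runs. No library of unlit cells was analysed here.

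The center library held 232144036 UMIs and the edge library 228512410. After cell calling and filtering, 9550 center cells and 10168 edge cells were kept, with medians of 17535 and 15885.5 UMIs and of 5660 and 5322 detected genes per cell. The kept cells held 183206958 UMIs in center and 179695152 in edge. Mitochondrial transcripts took a median of 2.24% of the UMIs of a center cell and 2.97% of those of an edge cell. Each group is 1 library, so no difference has a replicate check and no test was made. All 95% intervals cover counting error only, and genes are described as higher or lower by the size of their ratio.

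BMP4, the ligand that light was meant to switch on, was at nearly the same level in both libraries. It had 6249 UMIs in center, or 34.1 CPM (counts scaled to the library total), and 6772 UMIs in edge, or 37.7 CPM, a log2 ratio of edge to center of 0.14 (95% interval 0.09 to 0.19). With median-of-ratios scaling in place of the library total the ratio was 0.24. The counts do not separate transcripts of the transgene from those of the cell's own BMP4 gene. Whether the 3′ ends of the transgene's transcripts are counted as BMP4 at all is not known here. The near equality therefore holds for the counted transcripts and may not hold for the BMP4 that light switched on. The sums also mix cell classes that differ in BMP4, whose levels are given under other observations. Genes induced by BMP signalling were also close over all cells. The 10 measured members of that list had a median log2 ratio of 0.12, at percentile 81.0 among random lists matched on expression. MSX1 (5.61 and 27.8 CPM in center and edge), TBX3 (12.6 and 27.5 CPM) and SMAD7 (11.8 and 25.5 CPM) were at least 2-fold higher in edge. The ID genes, direct targets of the pathway, were within 2-fold, with log2 ratios of -0.18 for ID1, -0.65 for ID2, 0.11 for ID3 and -0.57 for ID4.

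Many genes of the primitive streak and nascent mesoderm, the tissues that form at the start of gastrulation, were far higher in edge, and several of them were nearly undetected in center. CER1, which encodes a secreted inhibitor of NODAL, had 78 UMIs in center and 18922 in edge, a log2 ratio of 7.94 (7.63 to 8.29). MIXL1, a homeobox gene of the streak, had 0.606 and 94.2 CPM, a log2 ratio of 7.27 (7.01 to 7.56). TBXT, which encodes the T-box factor brachyury, had 2 UMIs in center and 3720 in edge, a log2 ratio of 10.56 with an interval from 9.04 to 13.94. EOMES had 26 and 5718 UMIs, LHX1 12 and 7714, and MESP1, a regulator of early mesoderm, 294 and 8134. Of the 9 measured streak markers 7 were at least 2-fold higher in edge and none was lower. Their median log2 ratio was 7.27, above all 10000 matched random lists. FST (240 and 197 CPM) and SP5 (17.1 and 30.5 CPM) were within 2-fold. Of the 6 measured markers of paraxial and nascent mesoderm 5 were higher in edge, with LHX1 at 9.30, RSPO3 at 7.25 and APLNR at 6.25, and CYP26A1, a retinoic acid catabolic enzyme, was lower at -1.05, with 14650 UMIs in center and 6923 in edge. The median of that list was 5.54, above all random lists. GATA6 (5.73) and HAND1 (2.63), the 2 measured markers of lateral and extraembryonic mesoderm, were both higher in edge. The endoderm list had 3 measured members, of which CER1 and GATA6 were higher in edge and PRDM1 (0.92) was within 2-fold, with a median of 5.73 at percentile 99.99. SOX17, a regulator of endoderm and germ cells, had 1 UMI in center and 547 in edge, a log2 ratio of 8.54 with an interval from 6.64 to 14.43, and FOXA2 had 5 and 485 UMIs. TBXT, the 1 measured marker of axial mesoderm, is also a streak marker. In the GRCh38 annotation of GENCODE 29, TBXT lies on chromosome 6 at 166157656 to 166168700, MIXL1 on chromosome 1 at 226223618 to 226227054, EOMES on chromosome 3 at 27715949 to 27722711 and BMP4 on chromosome 14 at 53949736 to 53958761, all protein-coding. The build the authors counted against is not given in the sources used here.

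**Figure D1:**
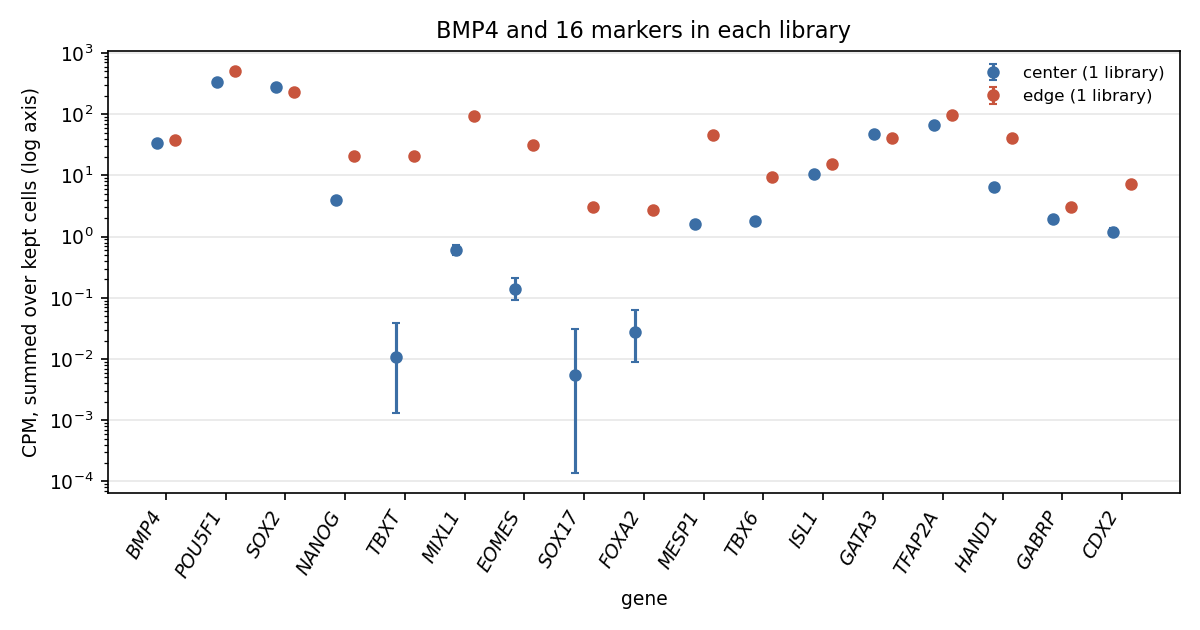
CPM of BMP4 and 16 markers, summed over the kept cells of each library, on a log axis, with exact 95% Poisson intervals (many are smaller than the point). BMP4 is at 34.1 CPM in center and 37.7 CPM in edge, while TBXT, MIXL1, EOMES, SOX17 and FOXA2 are each at 0.606 CPM or less in center.

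Over all kept cells, 8320 genes reached 20 CPM in 1 or both libraries. Of these, 143 were at least 2-fold higher in edge and 220 at least 2-fold lower, with the counting interval excluding equality. Genes within 1.5-fold made up 86.1% of those measured. Median-of-ratios scaling raised the median log2 ratio by 0.10 and turned the counts to 197 higher and 166 lower, so that 39.4% of the genes 2-fold apart were higher in edge with 1 scaling and 54.3% with the other. After CER1 and MIXL1, the largest ratios among the more abundant genes were those of NTS, which encodes the peptide neurotensin (5.53 and 181 CPM), the hyaluronan synthase HAS2 (4.55 and 64.0 CPM), the galanin gene GAL (26.7 and 259 CPM) and PLXNA2 (8.81 and 67.2 CPM). TDGF1, a co-receptor of NODAL, had 13.4 and 65.5 CPM. FAT3, CDH11, MGAT4C, NRG3 and RMST had log2 ratios between 2.07 and 2.19.

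Some of the genes listed for NODAL, WNT and FGF signalling were at least 2-fold higher in edge. NODAL itself had 89 UMIs in center and 5039 in edge, a log2 ratio of 5.84. Of the 4 measured genes of its list 3 were at least 2-fold higher, NODAL, CER1 and TDGF1, and the median of 4.06 lay above all random lists. All 3 are also in the streak or pluripotent lists, so this is not a separate result. NODAL and TDGF1 are the ligand and a co-receptor, not genes downstream of it. In the WNT list, LGR5 (4.79), NKD1 (1.93) and LEF1 (1.59) were at least 2-fold higher, 5 of 8 members were within 2-fold, and the median of 0.91 lay at percentile 100. In the FGF and ERK list, SPRY4 (2.46) and ETV4 (1.95) were higher while SPRED1 (0.20) and FGF2 (0.09) were not 2-fold apart, with the median of 1.07 at percentile 99.5. Of the 11 measured markers of pluripotent cells 4 were at least 2-fold higher in edge and 7 were within 2-fold, of which 4 had ratios below 0. NANOG was at 4.01 CPM in center and 20.6 CPM in edge, and L1TD1 (1.90), TDGF1 (2.28) and SFRP2 (1.27) were also at least 2-fold higher, whereas POU5F1 (0.59) and SOX2 (-0.30) were within 2-fold. The list's median was 0.55 over 11 members, at percentile 99.99.

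Amnion markers differed little over all cells. The amnion is the thin epithelium around the embryo, which BMP4 can induce in stem cells. Of 7 measured members HAND1 alone was at least 2-fold apart, and the median log2 ratio was 0.30, at percentile 98.1. GATA3 was at 47.1 CPM in center and 40.1 CPM in edge, TFAP2A at 67.5 and 96.0 CPM, ISL1 at 10.7 and 15.2 CPM and KRT7 at 29.7 and 23.5 CPM.

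**Figure D2:**
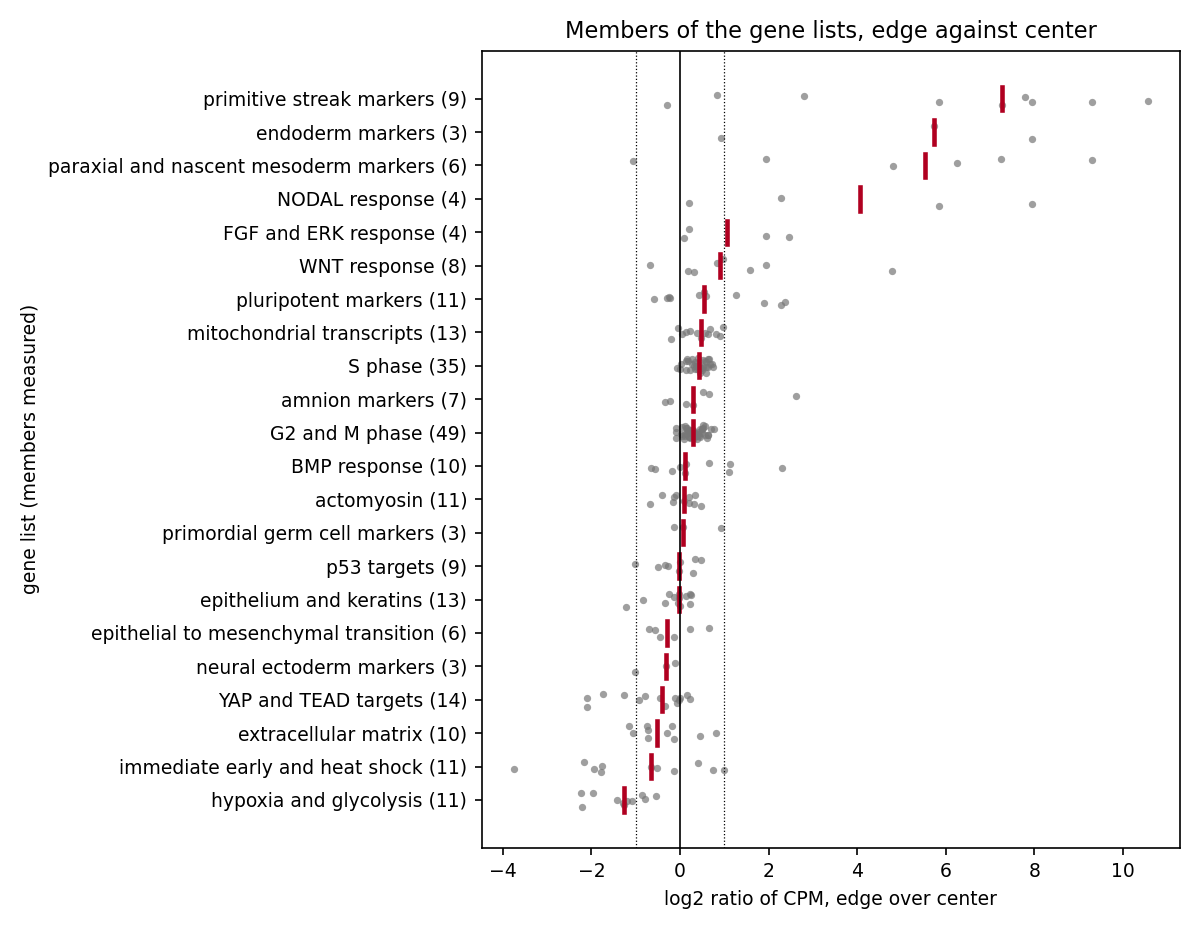
Log2 ratio of edge to center for each measured member (points) of the 22 gene lists with at least 3 members at 20 CPM or more, with the list's median as a red bar and dotted lines at a 2-fold difference. The medians run from -1.26 for hypoxia and glycolysis to 7.27 for primitive streak markers.

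The center library was higher in genes of hypoxia and glycolysis. LDHA, which encodes lactate dehydrogenase A, was at 928 CPM in center and 197 CPM in edge, a log2 ratio of -2.23 (-2.25 to -2.22). The collagen prolyl hydroxylase gene P4HA1 was at 152 and 33.0 CPM, the mitophagy gene BNIP3 at 284 and 72.8 CPM, and VEGFA at 27.9 and 10.3 CPM. Of 11 measured members 8 were at least 2-fold lower in edge, and the other 3, PDK1, EGLN3 and ENO1, had log2 ratios of -0.87, -0.79 and -0.53. The median of -1.26 lay below all 10000 random lists. Mitochondrially encoded transcripts showed the opposite, with a median log2 ratio of 0.48 at percentile 99.93 and none of 13 members 2-fold apart.

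Immediate early genes, which cells transcribe within minutes of a stimulus, were higher in center. FOSB was at 43.8 CPM in center and 3.24 CPM in edge, JUN at 108 and 24.0 CPM, FOS at 96.2 and 28.4 CPM, JUNB at 27.1 and 7.12 CPM and ATF3 at 33.0 and 9.54 CPM. The other 2 of the 7 measured, EGR1 (-0.65) and IER2 (-0.51), were within 2-fold. Of the 4 measured chaperone genes in the same list 3 went the other way, HSPH1 (0.99), HSPA8 (0.74) and HSP90AA1 (0.41), and DNAJB1 was at -0.14. Over its 11 members the list had a median of -0.65, below all random lists. Targets of YAP and TEAD, which respond to cell shape and tension, had a median of -0.40 at percentile 0.34. CCN1 (-2.10), ANKRD1 (-2.09), CCN2 (-1.74) and NUAK2 (-1.26) were at least 2-fold lower in edge and the other 10 of 14 were within 2-fold. In the amnion-like class described below 2 of 12 measured members were at least 2-fold higher in edge and 0 lower, with a median of -0.38. An unnamed cluster of 1180 center and 105 edge cells held 3306 of the 4639 ANKRD1 UMIs of the SOX2-rich center cells described below. ANKRD1 was at 134 CPM in its center cells and 108 CPM in its edge cells, CCN1 at 212 and 134 CPM and CCN2 at 120 and 75.4 CPM. Extracellular matrix genes had a median of -0.51 at percentile 0.02, with COL1A2 (-1.16) and COL1A1 (-1.07) at least 2-fold lower. Other genes with the lowest ratios were the NOTCH target HES4 (57.2 and 6.01 CPM), the thioredoxin inhibitor TXNIP (148 and 17.4 CPM), DLK1 (141 and 17.1 CPM), the stress-induced mTOR inhibitor DDIT4 (126 and 18.5 CPM), LRP2 (-2.58), COL11A1 (-2.44), TIMP3 (-2.31) and BTG2 (62.9 and 13.6 CPM).

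Cell cycle genes were slightly higher in edge. Of 35 S phase genes 34 had a log2 ratio above 0, with a median of 0.42, and of 49 G2 and M phase genes 46 did, with a median of 0.30. Both medians lay above all random lists, and no member was 2-fold apart. Among the remaining lists, epithelial to mesenchymal transition genes had a median of -0.30 (percentile 3.36) with VIM at -0.70 and CDH2 at 0.67. The median was 0.09 for actomyosin genes (percentile 66.1), -0.02 for p53 targets (55.9), -0.03 for epithelium and keratins (29.0) and 0.08 for germ cell markers (68.7). For epithelium and keratins and for p53 targets the sign flips with median-of-ratios scaling, and for epithelial to mesenchymal transition it flips, to 0.05, with mitochondrial and ribosomal protein genes left out of the total. CLDN4 (-1.21) and TNFRSF10B (-1.02) were the single members 2-fold apart in the epithelial and p53 lists. Of 3 measured neural ectoderm markers MAP2 was lower in edge (-1.02) and the median was -0.30 at percentile 5.60. No HOX gene of the list and no trophoblast or haemato-endothelial marker reached 20 CPM in either library.

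Clustering of both libraries together gave 11 clusters, of which 3 could be named from the marker lists. An amnion-like cluster, with KRT7, GATA3, WNT6, ISL1 and DLX5 among its leading genes, held 1162 center cells, or 12.2% (11.5 to 12.8%), and 1021 edge cells, or 10.0% (9.46 to 10.6%). The share was higher in center in each of 9 alternatives, where it reached at most 16.2% in center and 10.9% in edge. A streak/mesoderm-like cluster, led by CER1, LHX1, APLNR, RSPO3, MESP1 and MIXL1, held 1401 edge cells, or 13.8% (13.1 to 14.5%). It held 0 of 9550 center cells, which allows a share of up to 0.0314%. Its share of edge cells ran from 11.6% to 25.2% with other cell filters and clusterings, and at 18.5% and above it includes a second cluster, led by NODAL, that met the naming rule there. The third, a pluripotent-like cluster with NANOG, TDGF1, SFRP2 and L1TD1, held 2269 edge cells and 13 center cells. It was named on genes that differ between the libraries and nearly all its cells are from 1 library, so its size is not compared. Most other cells lay in clusters found almost entirely in 1 library, which may reflect the library and not a cell type. An unnamed cluster with the amnion markers GATA2 and BAMBI held 358 center cells (3.75%) and 14 edge cells (0.138%), and fell short of the 3 markers needed for a name. Clusters outside the UMI limits, which were not named, held 143 of 9550 center cells and 345 of 10168 edge cells. Cluster 10 of these, with 1 center and 193 edge cells and a median of 37416 UMIs, had the streak markers NODAL, SP5 and EOMES among its leading genes. The others had no listed marker among theirs. The unnamed and pluripotent-like clusters of usual depth with at least 200 CPM of SOX2, named SOX2-rich here, held 7887 center cells (82.6%) and 7387 edge cells (72.6%).

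**Figure D3:**
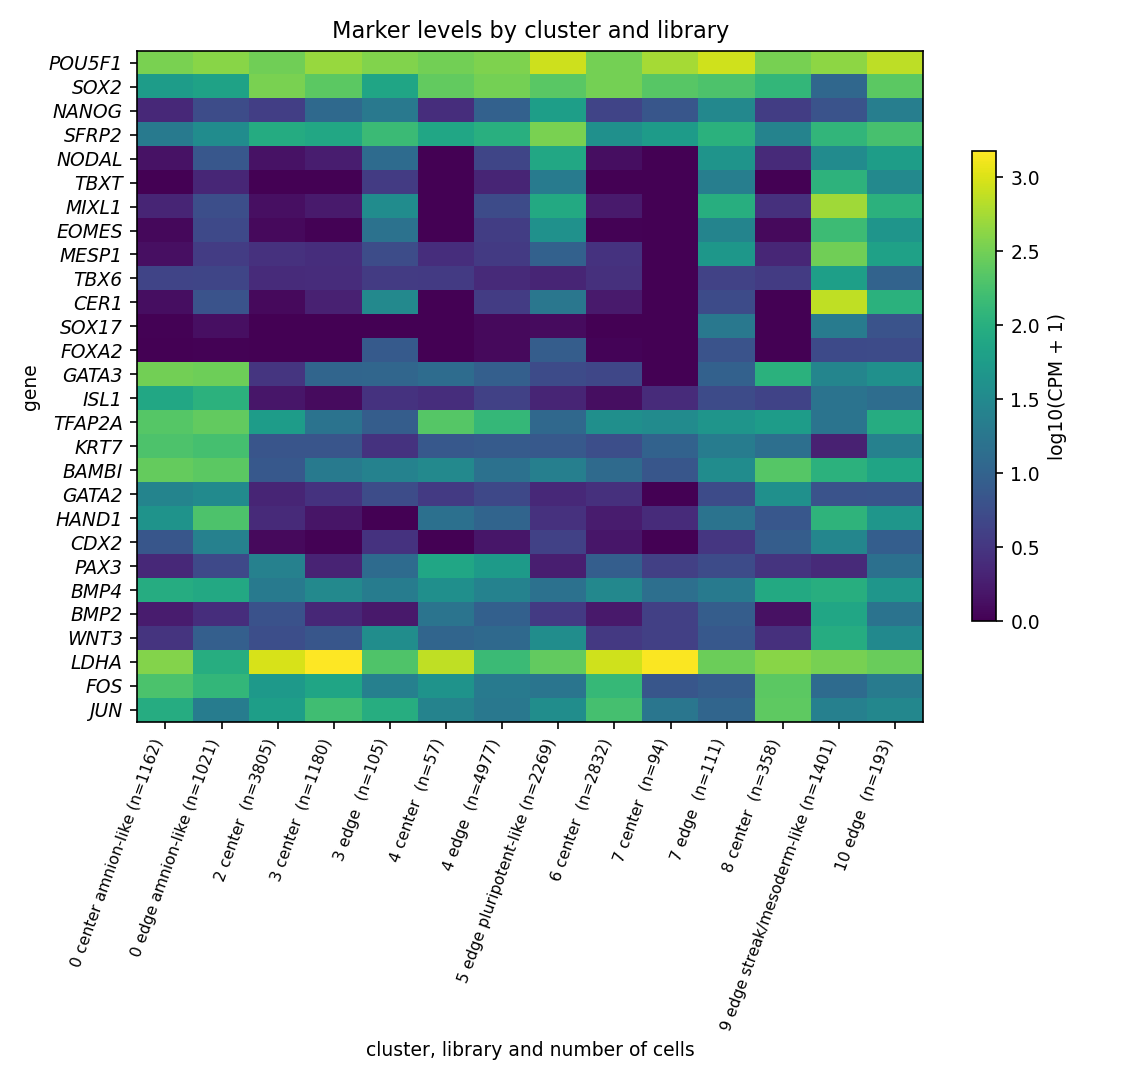
Levels of 28 genes, as log10 of CPM plus 1 (colour), in each cluster and library with at least 50 cells, with the cluster number, its name where it has one and the number of cells on the horizontal axis. GATA3, ISL1 and KRT7 are highest in cluster 0 of both libraries, and MIXL1, CER1 and MESP1 in cluster 9, which holds edge cells alone.

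Shares of cells with a UMI of a marker were compared after thinning each cell to 5000 UMIs, which left out 0 center cells and 11 edge cells. MIXL1 was seen in 0.251% of center cells and 16.9% of edge cells (16.2 to 17.7%), against 1.86% of the edge library's amnion-like cells, which stand for background from free RNA. The median depths before thinning were 14884 UMIs in those amnion-like cells and 15350 in streak/mesoderm-like cells, of which 77.6% had MIXL1. TBXT was seen in 1 of 9550 center cells and in 7.18% of edge cells (6.68 to 7.70%), with 0.490% of edge amnion-like cells as background. EOMES was seen in 0.0314% and 10.9%, MESP1 in 0.817% and 11.4%, TBX6 in 0.775% and 4.19%, and NANOG in 1.82% and 8.18%. SOX17 was seen in 0 center cells and in 0.748% of edge cells, and FOXA2 in 0.0209% and 0.955%. Background shares in edge amnion-like cells were 1.57% for EOMES, 0.979% for MESP1, 1.37% for NANOG, 0.196% for SOX17 and 0% for FOXA2. TBX6 was in 1.47% of edge and 1.12% of center amnion-like cells. The center library held no streak/mesoderm-like cells, so this TBX6 share is not background from such cells alone. Without thinning, MIXL1 was in 1.16% and 24.7%, TBXT in 0.0209% and 14.5%, EOMES in 0.272% and 20.6%, MESP1 in 2.91% and 17.6%, TBX6 in 3.40% and 9.68%, NANOG in 623 of 9550 and 2235 of 10168 cells, SOX17 in 0.0105% and 1.26%, and FOXA2 in 0.0524% and 2.95%. ISL1 was in 3.66% of center and 5.37% of edge cells and HAND1 in 2.30% and 10.8%. In the SOX2-rich center cells (median 17751 UMIs) the shares were 0.203% for ISL1 and 0.609% for HAND1. In the SOX2-rich edge cells (median 16155 UMIs) they were 1.21% and 2.87%. HAND1 was at 9.43 CPM in edge cells of cluster 4 and 1.86 CPM in those of cluster 5. CDX2 was in 0.513% and 3.04%, with 0.114% and 0.542% in SOX2-rich cells. GABRP was in 0.921% and 1.20%, with 0.723% and 0.596% there. Levels of CDX2 were 0.55 and 3.06 CPM in edge cells of clusters 4 and 5. GABRP was at 3.16 CPM in center cells of cluster 3 and 0.78 CPM in those of cluster 2. With such uneven levels, the shares of these markers in SOX2-rich cells are not background from free RNA alone. TFAP2A was in 21.0% of center cells and 28.8% of edge cells, and POU5F1 in 77.1% and 83.4%. For TFAP2A, 5.64% of the edge library's streak/mesoderm-like cells stand for background. SOX2-rich cells carried TFAP2A too, in 14.8% of center and 27.4% of edge cells, and edge cells of cluster 4 had it at 129 CPM. Its shares over all cells are therefore not those of amnion-like cells alone. Without thinning ISL1 was in 7.61% and 11.9%, HAND1 in 5.90% and 20.8%, CDX2 in 1.85% and 7.61%, GABRP in 2.93% and 3.24%, TFAP2A in 41.7% and 48.3% and POU5F1 in 97.4% and 96.7%. Of the 16 markers 2 had a lower share in edge, SOX2 with 66.2% and 56.4% and GATA3 with 11.2% and 10.5%, and the intervals of GATA3 overlapped. For comparison, SOX2 was in 4.36% of streak/mesoderm-like cells and GATA3 in 1.99% and 3.03% of SOX2-rich center and edge cells. Without thinning SOX2 was in 87.8% and 77.0%, and GATA3 in 18.4% and 19.2%, so no order is read from the shares of GATA3, nor from those of POU5F1, which also turn without thinning.

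Within the amnion-like class, amnion markers were slightly higher in edge as a list, with a median log2 ratio of 0.28 over 12 measured members at percentile 99.8. HAND1, a transcription factor of extraembryonic tissue, was at 42.0 CPM in center and 191 CPM in edge, IGFBP3 at 15.1 and 77.4 CPM and VTCN1 at 16.9 and 38.9 CPM. These were the 3 amnion markers at least 2-fold apart. GATA3 (-0.08), KRT7 (-0.15), DLX5 (0.04) and TFAP2A (0.25) were close. BMP response genes had a median log2 ratio of 0.02 over 11 members at percentile 47.4, with ID1 at 1159 and 1171 CPM. The ion channel gene TRPM3 (2.26), the growth factor gene PTN (24.1 and 110 CPM) and the fatty acid binding protein gene FABP5 (1.45) were also higher in edge. Of 8158 measured genes 108 were at least 2-fold higher in edge and 73 lower. The lower genes were led by TXNIP (162 and 21.1 CPM), SYNE1 (149 and 21.6 CPM), LDHA (385 and 93.1 CPM), PLCE1 (-1.85), BST2 (-1.59) and VIM (-1.59). All 7 measured hypoxia and glycolysis genes had ratios below 0, with a median of -0.86. At a finer clustering the class split into a cluster with 1046 center and 32 edge cells and another with 97 and 968. Which direction holds more genes depends on the cells taken into the class, with 97 higher and 119 lower without doublet removal, 100 and 104 with cells thinned before clustering and 110 and 108 with all barcodes of at least 2000 UMIs.

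**Figure D4:**
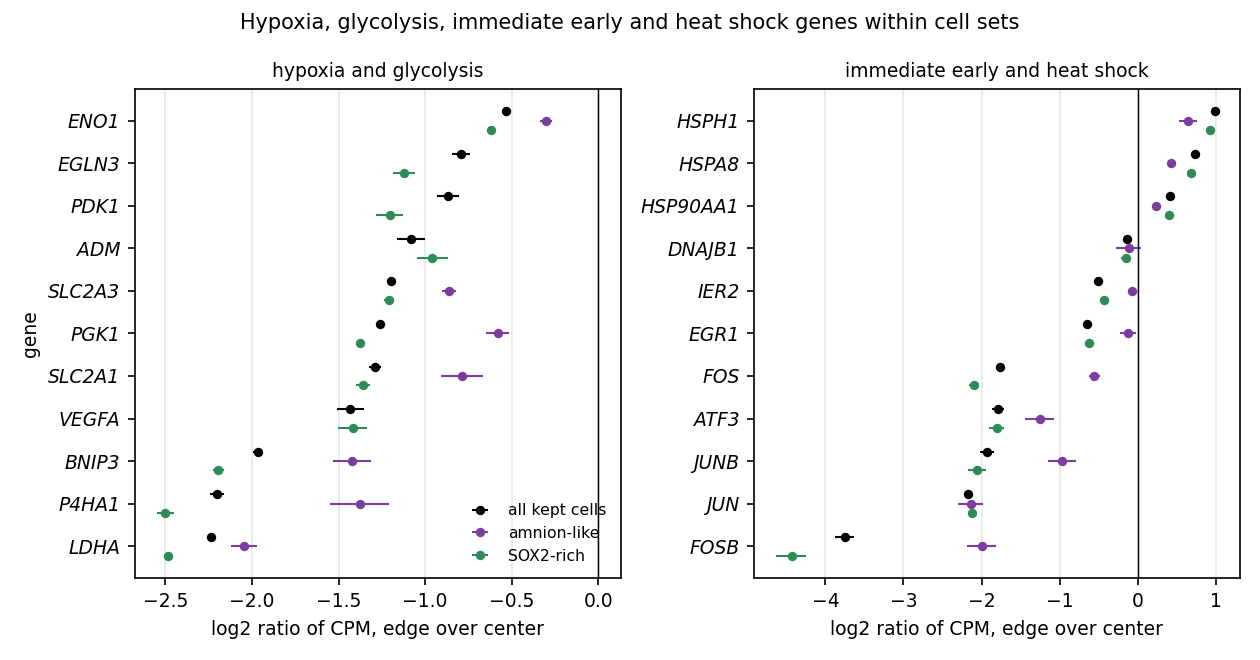
Log2 ratio of edge to center for members of the hypoxia and glycolysis list (left) and the immediate early and heat shock list (right) over all kept cells, within the amnion-like class and within the SOX2-rich clusters, with 95% counting intervals. Members under 20 CPM in both libraries of a set of cells are left out, and LDHA stands at -2.23, -2.05 and -2.49 in the 3 sets.

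The SOX2-rich cells were compared in the same way, a comparison chosen after seeing the data. Of 8221 measured genes 117 were at least 2-fold higher in edge and 214 lower. GAL (2.73), L1TD1 (153 and 670 CPM), NRG3 (1.99), KLHL4 (1.54) and KCND2 (1.51) were among the most different higher genes, and NANOG was at 4.45 and 25.4 CPM. NODAL, at 0.462 CPM in center and 28.5 CPM in edge, and MIXL1, at 0.495 and 30.8 CPM, were higher in edge in this set too. The pluripotent-like cluster 5 held 3396 of the 3724 NODAL UMIs and 3598 of the 4021 MIXL1 UMIs of these edge cells. The larger edge cluster 4 had 3.56 and 4.24 CPM, below the 6.30 and 4.80 CPM of the edge amnion-like cells. Cluster 5 also had EOMES at 39.6 CPM in its edge cells. At resolution 1.0 a cluster of 785 edge cells led by NODAL, with MIXL1, EOMES, TBXT and WNT3, was named streak/mesoderm-like. The pluripotent-like cluster then held 1611 edge cells, against 2269 as reported. The SOX2-rich edge cells may therefore include streak-like cells, so the higher NODAL and MIXL1 are not assigned to pluripotent cells. DLK1 (165 and 21.6 CPM), TXNIP (139 and 18.4 CPM), DDIT4 (138 and 19.1 CPM), P4HA1 (168 and 29.7 CPM), LDHA (1028 and 184 CPM) and TIMP3 (179 and 34.6 CPM) led the lower genes. The hypoxia and glycolysis median was -1.36, with 9 of 11 members at least 2-fold lower. Of the 66 genes at least 2-fold apart both in the amnion-like class and in the SOX2-rich cells, all 66 had the same direction in both. Both sets come from the same 2 libraries, so a difference between whole libraries, free RNA included, would move both alike. The shared direction is therefore not a replicate check. The SOX2-rich clusters differ in make-up between the libraries, since clusters 2, 3 and 6 held most of the center cells and clusters 4 and 5 most of the edge cells.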

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

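The tests in this part were chosen after the result was seen, except the one on free RNA for the hypoxia genes. The first signals below, in streak genes and in mitochondrial transcripts, come from barcodes that the comparisons do not use and lie above the limit that a count of 0 allows. The hypoxia and immediate early genes are weighed as patterns of the kept cells.

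Streak and nascent mesoderm genes were present in edge barcodes outside the kept cells. The 11 genes summed here are the members of these lists that were at least 2-fold higher in edge in kept cells. Their sum was 545 CPM in the 999 barcodes called but removed. It was 216 CPM in the 986 barcodes with 2000 UMIs up to the calling limit, against 484 CPM in kept cells. Edge barcodes with at most 100 UMIs had 436 CPM, so free RNA carried these transcripts. In the center library, no class of barcodes outside the kept cells exceeded 4.01% of the level in kept edge cells. Loss of such cells from center at calling or filtering was predicted to leave at least 25% there, and this did not occur. Depth does not account for the near absence either, since kept center cells held 102% as many UMIs as kept edge cells. No test here separates an effect of geometry from one of the place of the light, which differ together.

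Barcodes between 2000 UMIs and the calling limit were often poor in mitochondrial transcripts. In center 68.0% of them (626 of 921) had under 0.5% mitochondrial UMIs, and in edge 58.6% (578 of 986). Among kept cells 136 in center and 121 in edge were under that level. What these barcodes contain was not tested.

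The higher hypoxia and glycolysis genes in center could come from a different mix of classes. The median log2 ratio was -0.86 within the amnion-like class and -1.36 within the SOX2-rich cells, below the -0.5 set for rejecting that explanation. The shares of these sets therefore do not by themselves account for the difference. A different mix inside the sets cannot be excluded. The libraries fill different SOX2-rich clusters, and the amnion-like class splits largely by library at finer clustering. Free RNA could also add such transcripts, but the median ratio of their CPM in empty barcodes to that in kept cells was 1.03 in center, under the limit of 1.5. Oxygen supply, cell density and handling of the cultures were not measured, and no value here separates them.

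The higher immediate early genes in center could reflect stress during dissociation. The 4 measured heat shock members had a median log2 ratio of 0.57, in the opposite direction. That result cannot tell, because HSPA1A and HSPA1B, the most inducible members, were under 20 CPM and because dissociation can raise immediate early genes without heat shock genes. The shares of amnion-like and SOX2-rich cells do not by themselves account for the 7 immediate early genes as a set. Their median was -0.97 within the amnion-like class and -2.06 within the SOX2-rich cells. EGR1 (-0.12) and IER2 (-0.07) were close to 0 in the amnion-like class. A different mix inside these sets cannot be excluded. The libraries fill different SOX2-rich clusters, and the amnion-like class splits largely by library at finer clustering. The fixed list, which adds the heat shock members, had a median of -0.12 at percentile 8.28 in that class, with 3 of 11 members lower.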

How the results depend on the processing

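The minima of 10000 and 2000 UMIs, the wider amnion-like class and the SOX2-rich comparison were chosen after the result was seen. No paired analysis was possible because each group has 1 library. Of the main values 109 stayed close and 31 moved, and of the others 684 and 144. The balance of higher and lower genes turned over all cells with median-of-ratios scaling (197 and 166) and in the amnion-like class without doublet removal (97 and 119) and with thinned cells (100 and 104). With median-of-ratios scaling BMP4 had a log2 ratio of 0.24. With no CPM minimum 1542 genes were higher and 2691 lower and 113 list members were 2-fold apart, with 956 and 791 genes in the amnion-like class and 1192 and 2748 in SOX2-rich cells. With a 100 CPM minimum these were 26, 45 and 10, then 19 and 14, then 23 and 46. Genes measured over all cells numbered 33119 with no minimum and 2159 with 100 CPM, against 8320 as reported. The share of them that was 2-fold apart differed too, so the number measured does not alone explain the counts. The streak/mesoderm-like share of edge cells was 23.5% with at least 5000 UMIs, 22.4% with at least 10000, 12.8% with at least 2000, 12.4% with at most 10% mitochondrial UMIs, 25.2% without doublet removal, 18.5% at resolution 1.0 and 11.6% with separate clustering. The amnion-like share of center cells was 16.2% without doublet removal, 12.9% with at least 10000 UMIs, 14.9% with at least 2000, 15.4% with thinned cells and 15.9% with the GATA2 and BAMBI cluster added. That of edge cells was 10.9% without doublet removal, 8.53% with at least 10000 UMIs and 9.04% with at least 2000. For the streak/mesoderm-like shares of 18.5% and above, a second cluster led by NODAL, with 785 to 1538 edge cells, also met the naming rule, while the cluster led by CER1 held 1063 to 1272. Without doublet removal, with at least 2000 UMIs and with thinned cells, no separate GATA2 and BAMBI cluster was found. The amnion-like cluster then had BAMBI among its leading genes. The higher amnion-like shares of center cells in these settings therefore go with the merging of that cluster into the class. The cause of the other shifts in shares was not tested. Depth limits genes under 20 CPM, and class sizes depend on where the clustering draws its borders.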

Other observations

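The test in this part was chosen after the result was seen. A small group of edge cells had at least 2 UMIs of SOX17, 72 of 10168 or 0.708% (0.554 to 0.891%), of which 63 lay in the streak/mesoderm-like class. In center there were 0 of 9550, which allows up to 0.0314%. Within the class these 63 cells (median 14185 UMIs) differed from 1314 cells without SOX17 (median 15391 UMIs). They were higher in the germ cell genes NANOS3 (27.5 and 0.845 CPM) and TFAP2C (69.7 and 3.66 CPM), in the endoderm genes FOXA2 (28.5 and 2.91 CPM) and CER1 (1751 and 704 CPM), and in PRDM1 (145 and 4.74 CPM), which is in the lists of both. The endoderm gene GATA6 was close, at 269 and 254 CPM. They were lower in TBXT (29.5 and 115 CPM) and MESP1 (77.6 and 322 CPM). Of the 72 cells 48 had a UMI of PRDM1, 25 of FOXA2, 21 of TBXT, 18 of TFAP2C and 11 of NANOS3. If FOXA2 and NANOS3 marked the same cells, more than the 3.82 cells given by independent detection would hold both, and 1 did. With so few cells this cannot tell separate groups from 1 mixed group.

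BMP4 was higher in the amnion-like and streak/mesoderm-like classes than in the SOX2-rich cells. It was at 92.2 CPM in center and 81.8 CPM in edge within the amnion-like class, at 96.8 CPM in the streak/mesoderm-like class, and at 23.7 and 21.1 CPM in the SOX2-rich cells. The unnamed center cluster with GATA2 and BAMBI had 83.7 CPM. The streak/mesoderm-like class also had BMP2 at 73.7 CPM and WNT3 at 91.6 CPM. ID1 was at 257 CPM there, against 1159 and 1171 CPM in the amnion-like class and 354 and 347 CPM in the SOX2-rich cells.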
